A study of Homo sapiens with 6 samples.

How the data were processed

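Poly(A)-enriched or rRNA-depleted RNA of MOLM-13 cells was sequenced, and per the labels' protocols either enrichment is named without saying which was used. The labels' extraction text describes DNA, and how the RNA was handled before the library is not given in the sources used here. Per the labels, 3 libraries came from control cells and 3 from cells treated with 8p, and the treatment label placed each sample in its group. No vehicle is given for the control cells. The deposited table holds whole-number read counts per gene, which per the submitters' processing notes were made with HISAT2 2.0.5 and featureCounts 1.5.0-p3 on build hg38. DESeq2 1.20.0 and edgeR 3.22.5 are also named there without a role. The strand setting, the treatment of reads with several positions and the annotation release are not given in the sources used here. The coordinates deposited by the authors are those of GENCODE release 29 for 58724 of 58735 genes, and that release supplied GC content, transcript length and exon overlap.

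Counts were analysed as deposited, with all 6 samples and treatment as the only term. Of 58735 genes, 32140 had no read in any library, and 13822 passed edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 99.9% of the counts. Scaling used TMM factors in edgeR 4.0.16 with limma 3.58.1 under R 4.3.3. The test was edgeR's quasi-likelihood F test with robust dispersion and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. CPM values are TMM-scaled, except the sums of lymphoid and class II genes, which were scaled to library size alone. Errors of CPM values are the SD of 3 libraries unless an SE is named. Log2 fold changes are 8p over control with the standard error of the fit. The biological coefficient of variation was 8.98%. Replicate pairs of one group differed by 3.09 to 24.2 in chi-square per degree of freedom over genes, above sampling noise, so that no library was a copy of another, and pairs across groups by 331 to 380. Of the 8p libraries, replicate 2 differed most from the others.

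Folds against a group with no counts are lower bounds against a floor of 3 counts over the group, and folds with 1 to 3 counts carry an exact 95% interval of the count ratio, which covers counting error only, since the reads have no molecular identifiers. In a single library 3 counts are 0.128 to 0.200 CPM.

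There were 36 gene lists, fixed from textbook knowledge before the data were examined, with 658 different genes tested, 28 of them in more than 1 list. The lists covered RET and its ligands, the Mediator kinase module, receptor tyrosine kinases, the KMT2A-fusion programme, myeloid maturation, granule, stem and transcription factor genes, MAPK and STAT5 output, interferon and antigen presentation, cell cycle, p53, apoptosis, the BCL2 family, MYC and ribosome biogenesis, immediate-early genes, stress responses, lipid, glycolytic and mitochondrial metabolism, NF-kB, chromatin, ribosomal proteins, histones and markers of lymphoid, erythroid and stromal cells. Lists of at least 3 tested genes, 35 in all, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Of these, 9 were called higher, 9 lower and 17 not called. With an estimated correlation 4 calls held, those of DNA replication, mitosis, MYC and ribosome biogenesis, and the integrated stress response, and 14 were lost. A call lost in that setting does not by itself point to correlated members. The estimate lay below the preset 0.01 for MAPK output (-0.06), myeloid transcription factors (-0.04) and epithelial and stromal genes (-0.19). Correlation between members cannot explain why those calls were lost. The fry test asks whether a list moves one way, without comparing it with other genes.

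The rule for named genes, fixed before the data were examined, took RET, CDK8, CDK19, CCNC, FLT3, MYC, HOXA9, MEIS1, CDK6 and BCL2. It added the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 1 CPM and groups that do not overlap. From each called list it took the 3 members with the smallest p in the direction of the call, with up to 2 that passed against it, and from each other list the 2 members with the smallest p.

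Genes with 20% or more of their exonic bases in exons of another gene, 1637 of those tested (11.8%), were treated as uncertain, because the strand setting is not known. Members of families of near copies were treated in the same way.

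The test was tried on simulated counts with the means and library sizes of these samples, 13822 genes and 200 changed genes. It called 61.2% of genes changed by 1.5-fold, 70.1% of those changed by 2-fold and 97.0% of those changed by 4-fold with the right sign, and 7.32% of its calls were unchanged genes. In the real data far more genes, 10337, passed the threshold, so these rates need not hold there. The list test found the changed list and called 0 of 20 unchanged lists. Genes were drawn independently there, so this could not show how often correlated lists are called falsely. In the real lists the estimated correlation ranged from -0.19 for epithelial and stromal genes to 0.95 for mitochondrially encoded genes.

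Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors, library size alone, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, protein-coding genes alone, each library left out, and, for lists, fry and an estimated correlation. A correction for GC content and length (loess span 0.3), a fit without mitochondrial genes, scaling to the ribosomal protein genes and thinning to the smallest library were added after the data were examined, as were no filter, limma-voom and protein-coding genes alone for lists. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.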

Results

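RNA was measured by sequencing in MOLM-13, an established human acute myeloid leukaemia line that carries a rearranged KMT2A gene and an activated FLT3 receptor. The deposited gene counts covered 3 libraries of control cells and 3 libraries of cells treated with 8p, a synthetic compound that the labels call an inhibitor of RET and CDK kinases, with CDK8 named in the treatment label. The treated cells received 3.5 nM of 8p, against an IC50 of 7 nM, and both groups were incubated for 48 h. The control cells are called control or untreated and no vehicle is named, so an effect of a vehicle cannot be separated from that of 8p. The series description gives 3 independent biological replicates per group. Total counts were 23485628, 21356491 and 18834611 in the control libraries and 15249811, 16210861 and 14972069 in the 8p libraries, so every 8p library was shallower than every control library.

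The comparison of 8p with control addressed how inhibition of these kinases alters the transcriptome of the line. With 8p, genes of DNA replication, mitosis and ribosome biogenesis fell, as did most genes of the integrated stress response. MCM4, a subunit of the replicative helicase, fell from 901 ± 20.2 to 69.2 ± 1.77 CPM (TMM-scaled CPM, mean ± SD, n = 3 per group). PSAT1, an enzyme of serine synthesis, fell from 350 ± 19.0 to 15.1 ± 1.65 CPM. HLA class II genes, most genes of monocyte and granulocyte maturation and mitochondrially encoded transcripts rose, although the calls for these 3 lists were lost with an estimated correlation between genes. HLA-DRA, the alpha chain of HLA-DR, rose from 3.47 ± 0.310 to 227 ± 26.7 CPM, and CSF1R, the receptor of macrophage colony-stimulating factor, from 8.15 ± 1.00 to 120 ± 7.76 CPM.

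Among 13822 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5237 were higher and 5100 lower in the 8p libraries at the threshold of 0.05, and 3485 did not pass. Of these, 2879 were higher and 2418 lower by 2-fold or more. The 3 libraries of one group all lay outside the range of the other for 10638 of the tested genes (77.0%), where chance gives 10%. Changes are relative to a TMM scale on which the median of all genes was 0.03 on the log2 scale. With upper-quartile scaling this median was 0.22, and with scaling to the ribosomal protein genes, chosen after the data were examined, it was -0.09, and the signs of CCNC, MEIS1, CDK6 and BCL2, none of which passed the test, differed between these scalings.

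**Figure D1:**
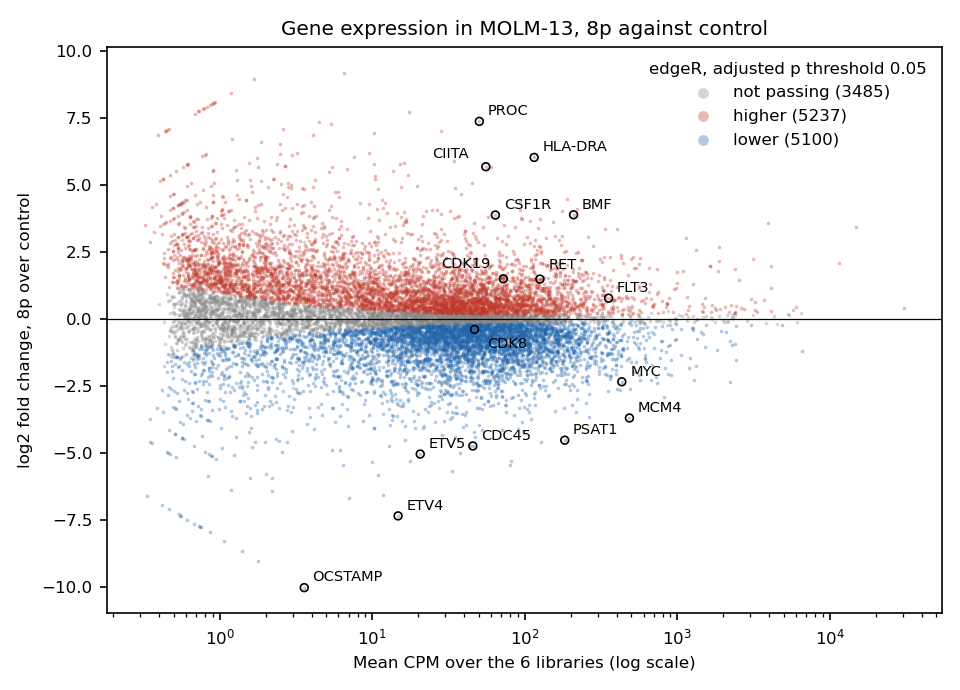
Log2 fold change of each tested gene, 8p over control, against its mean CPM over the 6 libraries on a log axis. Red points were higher (5237 genes), blue points lower (5100) and grey points did not pass (3485) in edgeR's test, and circled genes are named in the text. Diagonal streaks at low CPM are genes with no or few counts in one group.

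RET itself, the receptor tyrosine kinase among the named targets (ENSG00000165731; hg38 chromosome 10, 43077027 to 43130351, plus strand), rose from 66.1 ± 4.39 to 185 ± 1.44 CPM. Its log2 change was 1.48 ± 0.07 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.1e-12). Of its co-receptors and ligands, 3 further genes passed the count filter. The ligand gene ARTN rose from 1.68 ± 0.616 to 5.18 ± 0.148 CPM, NRTN fell and PSPN did not pass, the last 2 named to complete the list after their values were seen. For these 4 genes the counts were 2 higher, 1 lower and 1 not passing, also when adjusted over the list alone, and camera gave no call (adjusted p = 0.25).

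CDK8, the kinase of the Mediator complex (hg38 chromosome 13, 26254104 to 26405238, plus strand), fell from 53.3 ± 2.54 to 40.5 ± 4.84 CPM, a log2 change of -0.40 ± 0.10. That fall passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0012), but not with upper-quartile scaling, where the log2 change was -0.21 and the adjusted p 0.0550. Its paralogue CDK19 rose from 37.9 ± 1.27 to 107 ± 2.29 CPM (log2 change 1.49 ± 0.08), and MED13L, another subunit of the module, rose by 1.18 ± 0.08. CCNC, the cyclin partner of both kinases, was at 139 ± 16.3 CPM in control and 126 ± 3.77 CPM with 8p, and did not pass (edgeR adjusted p = 0.13). It passed as lower without control replicate 2, at a log2 change of -0.22 (edgeR adjusted p = 0.0297), without a filter, at -0.25 (0.0033), and with scaling to the ribosomal protein genes, at -0.26 (0.0136), but was at 0.051 with upper-quartile scaling (0.57). In the Mediator kinase module 3 of 6 genes rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone, and camera gave no call (adjusted p = 0.20).

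The KMT2A-fusion target programme moved in both directions. Of 22 tested genes, 10 rose, 5 fell and 7 did not pass, also when adjusted over the list alone (median log2 change 0.16, camera adjusted p = 0.20). FLT3, the receptor that is mutated in this line, rose from 262 ± 2.26 to 446 ± 4.42 CPM, and RUNX2, a transcription factor, rose by 1.90 ± 0.09 on the log2 scale. HOXA9, a homeobox gene of the programme, fell from 81.9 ± 10.4 to 60.9 ± 2.46 CPM, and MEF2C, a transcription factor, from 261 ± 11.8 to 143 ± 6.82 CPM. MEIS1, the partner of HOXA9, was at 57.1 ± 5.42 and 58.3 ± 2.48 CPM, the cell cycle kinase gene CDK6 at 314 ± 12.9 and 333 ± 2.85 CPM, and the survival gene BCL2 at 133 ± 3.801 and 139 ± 2.83 CPM in control and 8p, and none of these passed. With upper-quartile scaling MEIS1, CDK6 and BCL2 passed as higher (log2 changes 0.21, 0.27 and 0.25), with protein-coding genes only CDK6 and BCL2 passed as higher (0.17 and 0.15), and with a correction for GC content and length, chosen after the data were examined, these 2 genes passed as lower (-0.29 and -0.14). Without control replicate 3 the log2 change of MEIS1 was -0.07, and without 8p replicate 3 it was -0.02. Of the exonic bases of HOXA9, 27.0% lie in exons of another gene, so that its counts are uncertain.

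The largest rises among genes of at least 1 CPM were in SLC26A11, a sulfate transporter, with 1 count in the control libraries together and 612 in the 8p libraries, a count ratio of 839 (95% interval 150 to 33200, for counting error only). PROC, which encodes protein C of blood coagulation, rose from 0.593 ± 0.169 to 100.02 ± 8.44 CPM. S100A12, a calgranulin of granulocytes and monocytes, had no counts in control and 108 with 8p, at least 49.4-fold higher against a floor of 3 counts over the group. MIR3687-1 also had none, and 164 with 8p that were unevenly spread (1.26, 7.49 and 1.35 CPM in replicates 1 to 3), and MIR3648-1 rose from 0.160 ± 0.0747 to 34.8 ± 13.5 CPM. Both lie in ribosomal DNA on chromosome 21, which has near-identical copies elsewhere, so their counts are uncertain. Whether these reads came from the miRNAs or from other transcripts of that DNA was not tested. The 1 tested gene of the rRNA class outside the mitochondria also rose, by 5.78 on the log2 scale. A4GALT, a glycosyltransferase, had a count ratio of 188 (63.8 to 915), the cytokine receptor gene CRLF2 one of 164 (44.9 to 1361), and the galectin gene LGALS2 rose to 10.7 ± 0.773 CPM.

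The largest falls included 4 genes with no counts with 8p. OCSTAMP, which acts in osteoclast fusion, went from 454 control counts to none, at least 110-fold lower. AC004585.1, a lincRNA, was at least 54.2-fold lower, HSD11B1, a cortisone reductase, at least 42.3-fold lower, and ZIC2, a zinc finger transcription factor, at least 33.8-fold lower. ETV4 fell from 29.3 ± 0.324 to 0.174 ± 0.0805 CPM, the transsulfuration gene CBS from 14.01 ± 3.49 to 0.131 ± 0.117 CPM, and the calcium sensor gene NCS1 from 23.1 ± 0.478 to 0.242 ± 0.200 CPM. SPRY1, a feedback inhibitor of receptor tyrosine kinase signalling, had 275 control counts and 2 with 8p, 100.3-fold fewer for the library totals (27.5 to 832).

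The cell cycle lists fell as a whole. All 30 tested genes of DNA replication and G1/S were lower, also when adjusted over the list alone, with a median log2 change of -3.07 (camera adjusted p = 6.3e-41, and 0.0043 with an estimated correlation). MCM4 fell by 3.70 ± 0.07 on the log2 scale, the helicase subunit gene MCM6 fell by 3.32 ± 0.08 and CDC45, which joins the helicase at origins, fell by 4.75 ± 0.11. All 28 tested genes of mitosis and G2/M were lower, likewise over the list alone, with a median of -2.83 (camera adjusted p = 5.5e-36, and 0.0081 with an estimated correlation). CCNB1, the mitotic cyclin B1, fell from 187 ± 11.9 to 18.3 ± 0.360 CPM, the anaphase activator gene CDC20 from 178 ± 13.4 to 12.5 ± 1.28 CPM and the spindle checkpoint kinase gene BUB1 from 135 ± 2.06 to 14.5 ± 0.348 CPM. Cyclins, CDKs and CDK inhibitors outside those lists were mixed, with 9 higher, 10 lower and 6 not passing of 25, the same over the list alone (camera adjusted p = 0.49). With upper-quartile scaling their balance turned to 11 higher and 8 lower. CDK4, the G1 kinase, fell by 2.27 ± 0.11, and 43.2% of its exonic bases lie in exons of another gene.

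MYC, the transcription factor, fell from 723 ± 31.8 to 142 ± 7.37 CPM, a log2 change of -2.35 ± 0.07 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.3e-15). In the list of MYC and ribosome biogenesis genes, 25 of 26 fell and 1 did not pass, also when adjusted over the list alone, with a median of -1.95 (camera adjusted p = 5.7e-23, and 0.025 with an estimated correlation). SRM, an enzyme of polyamine synthesis, fell by 2.58 ± 0.07, ODC1, another, fell by 2.52 ± 0.07, and MRTO4, a ribosome assembly factor, fell by 2.64 ± 0.07. The ribosomal protein genes themselves gave no call. Of 86 tested, 29 were higher, 12 lower and 45 not passing, against 27 higher and 10 lower when adjusted over the list alone. Their median was 0.10, their mean -0.0004 and the camera direction up (adjusted p = 0.60), and with upper-quartile factors 49 were higher and 7 lower. With scaling to these genes themselves, which holds their summed counts level by design, 20 were higher and 31 lower (median -0.022). Without a filter the camera direction was down (0.70). RPS26 fell by 2.11 ± 0.07 and the paralogue gene RPL7L1 fell by 1.12 ± 0.06.

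Genes that report MAPK pathway output were mostly lower. Of 14 tested, 10 fell, 3 rose and 1 did not pass, with 4 higher and 10 lower when adjusted over the list alone. The median was -3.46 (camera adjusted p = 0.0173), and the call was lost with an estimated correlation (adjusted p = 0.15) and with limma-voom values (0.0741). ETV5, an ETS factor induced by ERK, fell from 40.0 ± 2.36 to 1.19 ± 0.336 CPM, and SPRED1, a pathway inhibitor, from 17.5 ± 2.03 to 1.46 ± 0.446 CPM. Against that direction, FOS, an AP-1 subunit, rose from 38.4 ± 2.51 to 219 ± 2.86 CPM, and PHLDA1 from 2.07 ± 0.184 to 10.8 ± 1.30 CPM. STAT5 targets gave no call, with 3 higher, 5 lower and 5 not passing of 13, the same over the list alone (camera adjusted p = 0.28). Among them the kinase gene PIM1 fell by 1.72 ± 0.13 and the cyclin gene CCND3 fell by 1.46 ± 0.07.

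Of 11 receptor tyrosine kinase genes, 7 rose and 4 fell, also when adjusted over the list alone (median 0.98, camera adjusted p = 0.0260, and adjusted p = 0.18 with an estimated correlation, 0.0564 without a filter and 0.217 with limma-voom values). AXL rose from 4.79 ± 0.558 to 66.8 ± 4.59 CPM and INSR, the insulin receptor gene, from 78.7 ± 3.18 to 155 ± 5.05 CPM, while EPHB4 fell by 2.45 ± 0.15 and TYRO3, a relative of AXL, fell by 3.40 ± 0.34. Short-lived immediate-early transcripts had 14 higher, 4 lower and 5 not passing of 23, the same over the list alone (median 0.70). Their call was marginal (camera adjusted p = 0.0484, and adjusted p = 0.19 with an estimated correlation). It was lost without control replicate 1 (0.0518), 2 (0.0614) or 3 (0.0677), without 8p replicate 1 (0.0510) or 2 (0.0542), and without the mitochondrial genes (0.0508). BTG2, an antiproliferative gene, rose by 2.75 ± 0.12, ZFP36, an mRNA decay factor, by 1.25 ± 0.09, and DUSP2, a phosphatase gene, fell by 1.57 ± 0.16.

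Monocyte and granulocyte maturation genes were mostly higher. Of 22 tested, 19 rose, 2 fell and 1 did not pass, also when adjusted over the list alone, with a median of 1.33, unchanged with S100A12 at its bound (camera adjusted p = 2.8e-10, and adjusted p = 0.0970 with an estimated correlation). CSF1R rose by 3.87 ± 0.10 on the log2 scale, CD36, a scavenger receptor, by 3.76 ± 0.08 and CYBB, the catalytic subunit of the phagocyte oxidase, by 3.66 ± 0.08. FCGR1A, the high-affinity Fc receptor, fell from 51.9 ± 2.18 to 8.11 ± 0.685 CPM, and FCGR2A from 28.4 ± 1.21 to 21.2 ± 1.76 CPM. FCGR1A has close copies and 24.6% of its exonic bases lie in exons of another gene, so its counts are uncertain.

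Of 18 myeloid transcription factor genes, 12 rose, 2 fell and 4 did not pass, also when adjusted over the list alone (median 0.66, camera adjusted p = 0.0123, and adjusted p = 0.15 with an estimated correlation). ETV6 rose by 1.61 ± 0.07, CEBPD by 1.67 ± 0.09 and CEBPA by 1.42 ± 0.08, the last with 43.4% of its exonic bases in exons of another gene. GFI1 fell by 0.32 ± 0.06 and MYB fell by 0.20 ± 0.07. With upper-quartile scaling neither of these 2 falls passed (log2 changes -0.13 and -0.0076), and that of MYB did not pass with protein-coding genes only (-0.11) or with the GC and length correction (-0.081). Primary granule genes gave no call, with 2 higher, 6 lower and 4 not passing of 12, the same over the list alone (camera adjusted p = 0.53), although their median of -0.12 was 0.06 with upper-quartile scaling. PRTN3, proteinase 3, fell from 3131 ± 119 to 1639 ± 21.1 CPM, and MS4A3 rose from 62.0 ± 4.07 to 107 ± 8.69 CPM. Of 7 stem and progenitor genes, 6 rose and 1 fell, also over the list alone, without a call (camera adjusted p = 0.15). The transcription factor gene GATA2 fell by 1.85 ± 0.11, and CD109, a surface protein, rose by 1.78 ± 0.11.

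All 9 tested HLA class II and related genes rose, also when adjusted over the list alone, with a median of 5.68 (camera adjusted p = 2.4e-16, and adjusted p = 0.0665 with an estimated correlation). HLA-DRA (hg38 chromosome 6, 32439842 to 32445046, plus strand) rose by 6.02 ± 0.12 on the log2 scale. HLA-DMA, which loads peptides, rose from 2.32 ± 0.335 to 118 ± 7.13 CPM, and CIITA, the transactivator of the class II genes, from 2.11 ± 0.330 to 109 ± 3.10 CPM. Of the exonic bases of CIITA, 23.4% overlap exons of another gene, and HLA genes share reads with their paralogues. HLA class I genes gave no call, with 8 higher, 3 lower and 3 not passing of 14, the same over the list alone (camera adjusted p = 0.19). HLA-E rose by 1.00 ± 0.07, and PSMB8, an immunoproteasome subunit with 20.6% exon overlap, fell by 1.26 ± 0.08.

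Interferon-stimulated genes did not move together. Of 20 tested, 7 rose, 6 fell and 7 did not pass, also when adjusted over the list alone, and the median of -0.0021, the mean of 0.09 and the camera direction of up differed in sign (camera adjusted p = 0.21). STAT2 rose from 30.2 ± 3.98 to 244 ± 6.43 CPM and IRF7 from 12.9 ± 0.781 to 43.8 ± 4.89 CPM. In the NF-kB and inflammatory list 10 genes rose, 5 fell and 1 did not pass of 16, the same over the list alone, without a call (camera adjusted p = 0.26). The chemokine gene CXCL8 rose by 3.18 ± 0.15 and CCL5 fell by 2.91 ± 0.11.

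Integrated stress response genes mostly fell. Of 25 tested, 18 were lower, 3 higher and 4 not passing, also when adjusted over the list alone, with a median of -1.62 (camera adjusted p = 1.1e-10, and 0.0216 with an estimated correlation). PSAT1 fell by 4.53 ± 0.09, PHGDH, which opens the serine pathway, fell by 4.18 ± 0.09 and SLC7A5, a transporter of large neutral amino acids, fell by 3.68 ± 0.08. SLC7A11, the cystine transporter, rose by 2.38 ± 0.09 and DDIT3, the transcription factor CHOP, by 1.11 ± 0.15, with 39.6% of its exonic bases in exons of another gene. In the unfolded protein response 10 of 17 genes fell, 4 rose and 3 did not pass, the same over the list alone (median -0.78, camera adjusted p = 0.0028, and adjusted p = 0.16 with an estimated correlation). XBP1, a transcription factor of this response, fell from 395 ± 25.0 to 35.04 ± 1.74 CPM, the chaperone gene CALR fell by 2.07 ± 0.07 and the chaperone gene HSPA5 fell by 1.54 ± 0.08, while the sensor kinase gene ERN1 rose by 1.49 ± 0.13 and EDEM1 by 1.33 ± 0.07. Of 15 heat shock genes 13 fell, 1 rose and 1 did not pass, also over the list alone (median -1.50, camera adjusted p = 6.2e-10, and adjusted p = 0.15 with an estimated correlation). HSP90AB1 fell from 3720 ± 124 to 732 ± 34.6 CPM, HSPA8 fell by 2.27 ± 0.07 and HSPB1 fell by 2.59 ± 0.09, and the co-chaperone gene BAG3 rose by 0.73 ± 0.12.

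All 30 tested nuclear genes of oxidative phosphorylation fell, also when adjusted over the list alone, with a median of -1.06 (camera adjusted p = 1.5e-08, and adjusted p = 0.26 with an estimated correlation). ATP5MC3, a subunit of ATP synthase, fell by 1.72 ± 0.07, NDUFS1, of complex I, fell by 1.57 ± 0.07 and UQCRQ, of complex III with 20.8% exon overlap, fell by 1.99 ± 0.09. Hypoxia and glycolysis genes gave no call, with 6 higher, 12 lower and 4 not passing of 22, the same over the list alone (camera adjusted p = 0.25). LDHA, lactate dehydrogenase A, fell from 1434 ± 28.8 to 190 ± 8.88 CPM, and PFKFB3, which makes an activator of glycolysis, rose from 39.4 ± 2.77 to 217 ± 14.1 CPM. Cholesterol synthesis and uptake had 4 higher, 14 lower and 5 not passing of 23, the same over the list alone, without a call (camera adjusted p = 0.0914), although the list was called lower without a filter (0.0027) and with limma-voom values (0.0456). FDPS, of the mevalonate pathway, fell by 1.54 ± 0.08 and INSIG1, a regulator of sterol sensing, fell by 0.93 ± 0.07. Of 9 cholesterol efflux and LXR target genes, 3 rose and 6 fell, also over the list alone (camera adjusted p = 0.15), and the list was called lower without control replicate 3 (0.0492) and with the GC and length correction (0.0283). SCD, a fatty acid desaturase, fell by 2.60 ± 0.07 and SREBF1, a lipogenic transcription factor, fell by 2.44 ± 0.08.

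Of 20 p53 target genes, 12 rose, 4 fell and 4 did not pass, also when adjusted over the list alone (median 0.50, camera adjusted p = 0.0118, and adjusted p = 0.16 with an estimated correlation). TP53INP1 rose from 7.70 ± 0.787 to 73.9 ± 4.66 CPM and ZMAT3 by 1.89 ± 0.09, while SESN2 fell by 1.00 ± 0.11 and AEN, an exonuclease gene, fell by 0.63 ± 0.09. In the apoptosis and DNA damage list 12 of 19 genes fell, 6 rose and 1 did not pass, the same over the list alone (median -1.07, camera adjusted p = 0.0018, and adjusted p = 0.14 with an estimated correlation). The members with the strongest evidence of a fall act in DNA repair: EXO1 fell by 4.07 ± 0.14, BRCA1 fell by 2.66 ± 0.09 and the histone gene H2AFX fell by 2.16 ± 0.07. The caspase genes CASP8 and CASP9 rose by 0.97 ± 0.09 and 1.04 ± 0.11. The BCL2 family gave no call, with 4 higher, 4 lower and 5 not passing of 13, the same over the list alone (camera adjusted p = 0.37), a median of -0.06 and a mean of 0.15. BMF, a pro-apoptotic BH3-only gene, rose from 26.5 ± 1.63 to 391 ± 9.81 CPM, and BID, another, fell from 132 ± 7.12 to 58.9 ± 3.51 CPM. DNA methylation and chromatin regulators had 8 higher, 17 lower and 3 not passing of 28, against 9 higher and 17 lower over the list alone, without a call (camera adjusted p = 0.0914), although the list was called lower without control replicate 3 (0.0477), without a filter (0.0031) and with the GC and length correction (0.0055). UHRF1, which recruits the maintenance methyltransferase, fell by 2.30 ± 0.08 and that enzyme's gene DNMT1 fell by 1.44 ± 0.07.

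**Figure D2:**
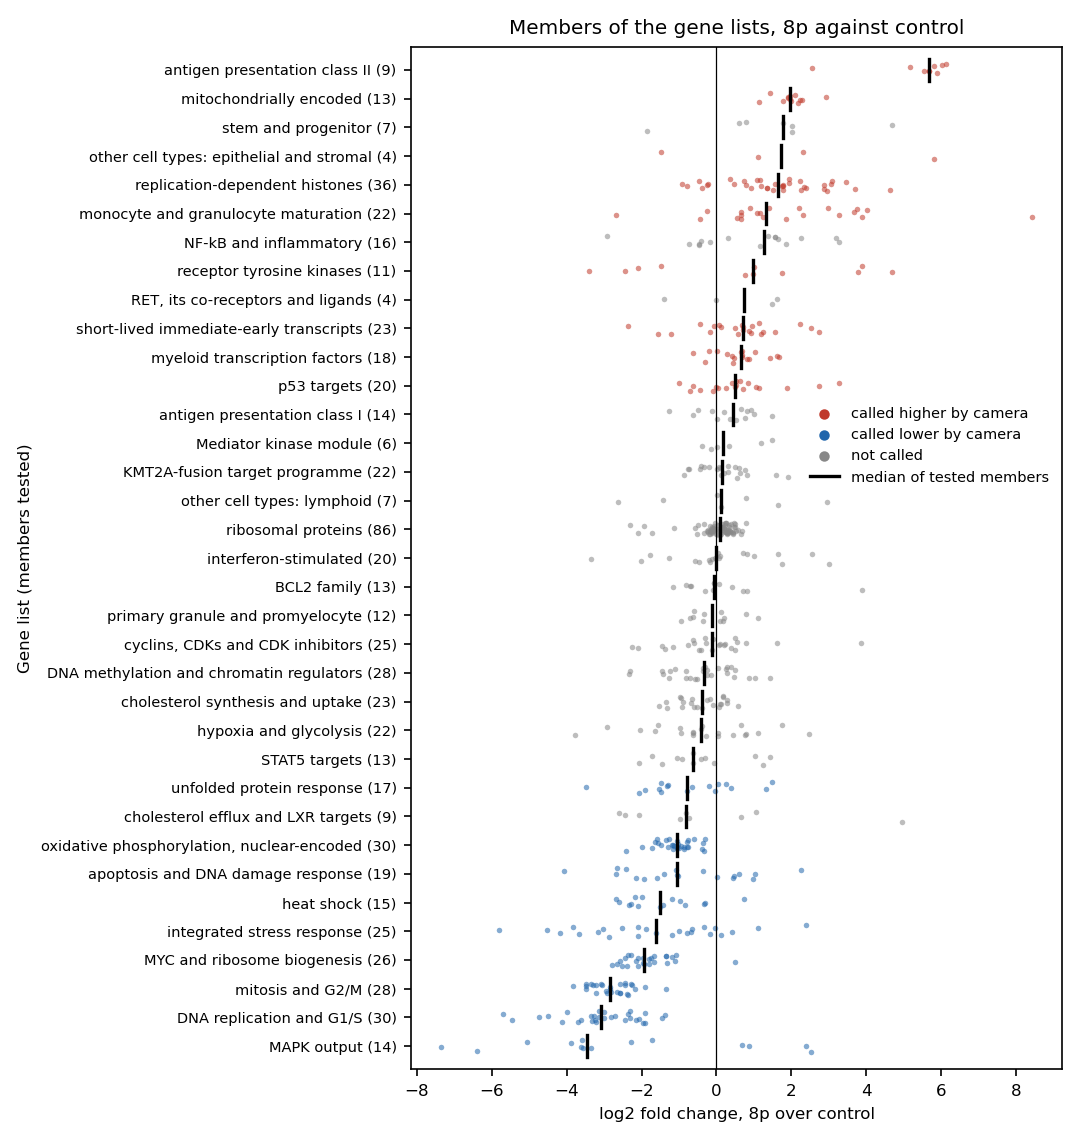
Log2 fold change, 8p over control, of each tested member of the 35 gene lists tested, with the number of tested members in brackets and the median as a black bar. Lists called higher by camera are red, lists called lower blue and others grey, from a median of -3.46 for MAPK output to 5.68 for class II antigen presentation.

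All 13 mitochondrially encoded mRNAs rose, also when adjusted over the list alone, with a median of 1.97 (camera adjusted p = 0.0029, and adjusted p = 0.44 with an estimated correlation). MT-CO1, of complex IV, rose from 4340 ± 247 to 18562 ± 4637 CPM, MT-ND6, of complex I, by 1.90 ± 0.13 and MT-ATP8 by 2.91 ± 0.10, the last with 22.2% of its bases in another gene. The mitochondrial genome took 1.77 ± 0.132% of the counts in control and 8.80 ± 2.07% with 8p, where replicate 2 stood apart at 6.42% against 10.004% and 9.98% in replicates 1 and 3. Of 71 replication-dependent histone genes 36 passed the count filter, which can keep a gene of few counts through the group where it is high. Of these 36, 26 rose, 1 fell and 9 did not pass, the same over the list alone (median 1.65, camera adjusted p = 1.1e-04, and adjusted p = 0.15 with an estimated correlation). HIST1H2AC rose from 2.93 ± 0.0720 to 73.3 ± 2.88 CPM, HIST1H2BK by 2.88 ± 0.11 and HIST1H4I by 2.96 ± 0.12. The fall of HIST2H2AC was marginal (edgeR's quasi-likelihood test, adjusted p = 0.0466) and did not pass without control replicate 1 (0.0644), 2 (0.123) or 3 (0.1002), without 8p replicate 3 (0.160), with upper-quartile scaling (0.107), DESeq2 (0.0623) or the replicate block (0.0550), with protein-coding genes only (0.0572) or in thinned libraries (0.0516). Histone genes are near copies of each other, their counts are uncertain, and their rise went with the higher mitochondrial share in the same libraries.

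Markers of other cell types moved in both directions. Of 7 lymphoid genes, 3 rose, 2 fell and 2 did not pass, also when adjusted over the list alone (camera adjusted p = 0.61). IL7R rose from 5.76 ± 0.857 to 18.1 ± 0.940 CPM and TRAC fell from 12.9 ± 0.750 to 4.87 ± 1.43 CPM. Of the erythroid and megakaryocytic list 1 gene passed the count filter, so the list was not tested. That gene, EPOR, fell from 25.4 ± 1.41 to 12.6 ± 0.447 CPM. Of 4 epithelial and stromal genes 3 rose and 1 fell, the same over the list alone (median 1.72, camera adjusted p = 0.0159, and adjusted p = 0.15 with an estimated correlation and 0.227 with limma-voom values). These were PECAM1, which blood cells also express and which rose from 111 ± 2.67 to 553 ± 37.2 CPM, the collagen gene COL1A1, from 0.542 ± 0.297 to 31.8 ± 5.99 CPM, and the keratin genes KRT8, which rose by 1.11 ± 0.39, and KRT18, which fell by 1.47 ± 0.19. The rise of KRT8 did not pass without control replicate 2 (edgeR adjusted p = 0.101) or without 8p replicate 1 (0.0604).

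**Figure D3:**
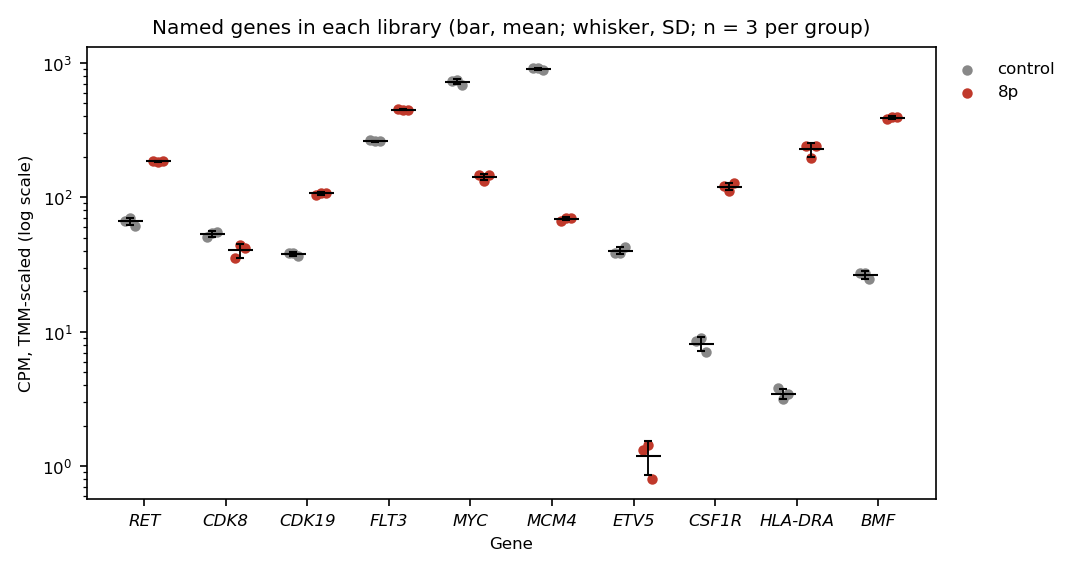
TMM-scaled CPM of 10 named genes in each library on a log axis, control in grey and 8p in red, with the mean as a bar and the SD as a whisker (n = 3 per group). For each of the 10 genes the control and 8p libraries do not overlap, as for RET at 66.1 against 185 CPM and ETV5 at 40.0 against 1.19 CPM.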

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

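The GC and length correction, the fit without mitochondrial genes, the scaling to ribosomal protein genes, the thinning and, for lists, no filter, limma-voom and protein-coding genes only were chosen only after the results were seen. Under every alternative run, the 4 counts of genes (higher and lower, at any fold and at 2-fold or more) stayed within 1.5 times their values. The counts without 8p replicate 2, the library apart from the others, were 5295 higher and 5336 lower, and without mitochondrial genes 5174 and 5136. Replicate numbers did not pair the samples (correlations of same-numbered deviations -0.01, -0.02 and -0.04, and no sample was closest to its own number), and with the number as a block 5082 genes were higher and 5022 lower. Higher genes made up 50.7% of calls, 59.4% with upper-quartile factors and 44.6% with ribosomal protein scaling. Of the calls shared with an alternative, 36 turned direction with the GC and length correction and 0 with the others.

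Lists were not run with DESeq2. Under the alternatives run for lists, the direction reversed for ribosomal proteins without a filter (adjusted p = 0.70, down) and for no other list. Without a filter the call of receptor tyrosine kinases was lost (0.0564), and cholesterol synthesis (0.0027) and chromatin regulators (0.0031) were called. With limma-voom the calls of receptor tyrosine kinases (0.217), MAPK output (0.0741) and stromal genes (0.227) were lost, and cholesterol synthesis was called (0.0456). Medians and counts did turn in lists without a call: with upper-quartile factors the medians of cyclins and CDKs (from -0.12 to 0.064), primary granules (from -0.12 to 0.064), the BCL2 family (from -0.064 to 0.12) and interferon-stimulated genes (from -0.0021 to 0.19) changed sign, and with ribosomal protein scaling that of lymphoid markers (to -0.014). Ribosomal proteins also turned with that scaling, from 29 higher and 12 lower to 20 and 31, with a median of -0.022. The interferon median also changed sign with library size alone (to 0.0068). With an estimated correlation, adjusted p was 0.0665 for class II, 0.0970 for monocyte and granulocyte maturation, 0.14 for apoptosis and DNA damage, 0.149 for myeloid transcription factors and histones, 0.1503 for MAPK output, heat shock and stromal genes, 0.159 for the unfolded protein response, 0.164 for p53 targets, 0.179 for receptor tyrosine kinases, 0.189 for immediate-early transcripts, 0.259 for oxidative phosphorylation and 0.441 for mitochondrially encoded genes. With fry, which sets no list against other genes, 16 further lists passed, at 5.3e-05 for STAT5 targets, 5.7e-05 for cholesterol synthesis and for NF-kB, 9.2e-05 for stem and progenitor genes, 1.8e-04 for the Mediator module and for hypoxia, 2.4e-04 for RET and its ligands, 3.0e-04 for the KMT2A-fusion programme, 3.5e-04 for class I, 4.0e-04 for cholesterol efflux, 7.6e-04 for interferon-stimulated genes and for chromatin regulators, 0.0014 for cyclins and CDKs, 0.0024 for primary granules, 0.0034 for the BCL2 family and 0.0351 for lymphoid markers. Every tested list but that of ribosomal proteins (fry adjusted p = 0.77) thus passed fry. As 74.8% of all tested genes passed the gene threshold, a pass with fry does not single out a list. The GC and length correction gave calls for chromatin regulators (0.0055) and cholesterol efflux (0.0283), and leaving out the mitochondrial genes ended that of immediate-early transcripts (0.0508). With 1 library left out, adjusted p ranged from 0.0350 to 0.0677 for immediate-early transcripts, from 0.0477 to 0.108 for chromatin regulators and from 0.0492 to 0.207 for cholesterol efflux. The cause was not tested.

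Of the 128 named genes, 4 that did not pass changed sign. CCNC was at 0.051 with upper-quartile factors and 0.039 with the GC and length correction. Without a filter, MEIS1 was at -0.089, CDK6 at -0.033 and BCL2 at -0.055. With ribosomal protein scaling these were at -0.105, -0.046 and -0.068, and with the GC and length correction CDK6 was at -0.29 and BCL2 at -0.14. With 1 library left out, MEIS1 ranged from -0.070 to 0.059. Among named genes 16 values fell short of the threshold under an alternative, for HIST2H2AC, KRT8, CDK8, GFI1 and MYB. Another 8 passed it anew in the direction of the main fit, for CCNC, CDK6, BCL2 and MEIS1, and the 2 values of CDK6 and BCL2 with the GC and length correction passed it in the other direction. The cause was not tested. The pseudocount alternative was not run, as the table holds counts. Depth limits genes near 3 counts per group, and the thinned libraries gave 5138 higher and 4971 lower genes.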

Other observations

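Tests of RNA without a poly(A) tail, of mitochondrial rRNA against mRNA, of lymphoid markers and of lineage genes, and the gene families below, were chosen only after the results were seen. The lymphoid test was redrawn then, with new genes and bounds.

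Among gene families with at least 15 tested members, those of mitochondrial ribosomes and import fell. Of 49 MRPL genes of the large mitochondrial ribosomal subunit 45 were lower and 0 higher, with a median log2 change of -1.23, and of 28 MRPS genes of the small subunit 26 were lower, with a median of -1.07. All 15 TIMM genes of inner membrane import were lower (median -1.58), as were 19 of 21 NUP genes of the nuclear pore (median -1.26). In contrast, of 356 ZNF genes, which encode zinc finger proteins, 187 were higher and 64 lower (median 0.40). The camera adjusted p was 3.7e-11 for MRPL, 2.0e-07 for MRPS, 1.1e-06 for TIMM, 2.2e-06 for NUP and 0.0195 for ZNF, and with an estimated correlation none passed (adjusted p from 0.27 for TIMM to 0.38 for MRPL). With upper-quartile factors 3 MRPL genes were higher, and the medians of these families kept their signs under each scaling.

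Long noncoding RNA also leaned upward. Of 501 lincRNA genes 278 were higher and 62 lower (median 0.78), and of 626 antisense genes 301 were higher and 67 lower (median 0.78), against 4105 higher and 4790 lower of 11500 protein-coding genes (median -0.07). With upper-quartile factors the protein-coding genes turned to 4963 higher and 4005 lower (median 0.12), while the lincRNA and antisense medians rose to 0.97 and 0.96. On the TMM scale, of 77 sense-intronic genes 48 were higher and 5 lower (median 1.05), and of 41 sense-overlapping genes 27 and 1 (median 1.09). The lean was not particular to long noncoding RNA, and its cause was not tested. Of 89 unprocessed pseudogenes 49 were higher and 11 lower (median 0.80), and of 196 transcribed unprocessed pseudogenes 115 and 23 (median 0.78). Of 394 processed pseudogenes 96 were higher and 101 lower, which turned to 120 and 89 with upper-quartile factors. The share of counts in lincRNA was 0.240 ± 0.0032% in control and 0.419 ± 0.0107% with 8p (SD, n = 3). Antisense genes cannot be told from their partners without the strand setting. By chromosome, the nuclear chromosomes showed no shift (camera adjusted p = 0.97 for each), and 32 of 33 mitochondrial genes were higher.

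Mitochondrial and histone RNA were both higher in the 8p libraries, with a mitochondrial share 4.97 times that of control and an rRNA share from that genome 11.1 times as large. Degradation that favours short transcripts would lower long genes against short ones, and no such trend was seen. Spearman's rho of log2 change with gene length was 0.035 across genes, which are not independent replicates. As 10337 of 13822 tested genes passed the threshold, other changes could hide such a trend, so degradation is not excluded. An even rise in mitochondrial transcription as the whole cause is argued against, because the 2 rRNAs rose further than the 13 mRNAs, by a mean of 3.50 against 1.98 (SD 0.42), a difference of 1.52. A candidate explanation is that more RNA without a poly(A) tail was carried through library preparation. The summed CPM of nuclear RNA of that kind (snRNA, snoRNA, scaRNA and RN7SL2, with histones left out) rose by 1.07 on the log2 scale. It went from 58.6 (SD 2.80) to 122.8 (SD 4.82), although snRNA, at 2.12, and snoRNA, at 0.37, differed. The explanation leaves open the rise of the mitochondrial mRNAs, most of which have tails, and an effect of 8p itself on these RNAs, which was not tested apart from it. Whether the counted histone transcripts had a tail was not measured. Of 36 tested histone genes 26 rose, while all 30 tested genes of DNA replication and G1/S fell. Among 8p replicates 1 to 3 the mitochondrial share was 10.004, 6.42 and 9.98%, but the snRNA share was 0.0039, 0.0040 and 0.0040%. HIST1H2BK (93.0, 74.4 and 94.1 CPM) and HIST1H4I (54.1, 42.7 and 52.8 CPM) were lower in replicate 2. HIST1H2AC (72.3, 71.1 and 76.6 CPM) differed less. So these RNAs did not all vary together, though this rests on 1 library.

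The HLA class II rise was weighed against 3 technical explanations. B or T cells in the 8p cultures as the whole cause are argued against. All 15 genes of the lymphoid list, summed with every immunoglobulin and T cell receptor gene, rose by 41.4 CPM (SE 5.80), or 1.72% of the rise of the class II list, and 7.79% of the rise of that list without CD74 (9.97% with 2 SE added). These sums were scaled to library size alone. The last value lies only just under the bound for this test, which was set after the results were seen. No counts of CD79B, PAX5, CD2, CD8A or LCK were found with 8p. A small share of such cells is not excluded, since 3 of 7 tested genes of the list and all 5 tested immunoglobulin genes rose. A shift with GC content or gene length is argued against, because the class II median was 5.82 after correction for both. Another line in place of MOLM-13 stays open. The log2 changes of HOXA9, HOXA10, MEIS1, FLT3 and RET had a median size of 0.74, but 4 of these 5 genes belong to the KMT2A-fusion programme, which other KMT2A-rearranged lines share. An effect of 8p on class II transcription, together with the rise of CIITA, and an effect of a vehicle also stay open.

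The 6 samples can be split into 3 and 3 in 10 ways, and 1 split, the real one, gave as many genes. These splits are too few for a share under 0.05. The real split gave 10337 genes past the threshold of edgeR's quasi-likelihood test, and the highest of the others gave 0, with at most 48 genes at an unadjusted p under 0.05.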
